A study of Picea engelmannii x Picea glauca with 20 samples.

How the data were processed

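Bark RNA of 20 resistant and 20 susceptible trees was compared on 20 two-colour arrays of 25344 spots, of which 21843 carried spruce probes and 3501 were controls. Per the labels' protocols, the tissue was frozen in the field and the RNA labelled by reverse transcription with dye-specific primers and a dendrimer kit. Per the file headers, the authors quantified the scanned images with version 6.0.1 of the image software, which gave 40 files, 1 per array and dye. Each deposited file holds the mean and median intensity of every spot and its local background on a linear scale, not normalised. The authors also deposited a value table, whose processing is not given in the sources used here. Against the scanner intensities of bright spots the table's columns had slopes near 1 or -1 according to the dye of the resistant tree. The authors' table therefore holds log2(susceptible / resistant), turned for the dye on every array, and its column medians lay between -0.00922 and 0.0153. It gives a value for 18725 of the spruce probes on every array and none for the other 3118, on a basis that stayed unknown, as did its exact normalization. WS02611_L17 is among the probes without a value.

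The labels name 40 different trees, whereas the series' design text speaks of a dye flip for each pair on 2 arrays. The labels were followed, and each array was taken as 1 independent pair of trees. Replicates were numbered in accession order within each dye orientation, and the numbers pair nothing. Whether trees are related is not given in the sources used here. The probe name column was blank on 2 arrays, and their spots were named by position. The total log intensity of every array correlated with the mean of the others by position with r from 0.903 to 0.952, against 0.0697 to 0.104 when shifted by 1 spot.

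Spot means were corrected for the median local background with normexp and an offset of 50, and log2(Cy5 / Cy3) was normalised within each array by loess, with no weight on control spots. Spots that the image software marked as bad, 31 to 411 spruce spots per array, were left out, and spots marked as empty were kept. Control spots were left out after normalization. A linear model with a resistant-against-susceptible term, signed by the dye of the resistant tree, and a dye effect was fitted to each probe with lmFit and eBayes of limma 3.58.1 in R 4.3.3. Two-sided p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Levels per tree were taken from the channels after loess and Aquantile. A spot was above background when its mean exceeded the median local background by 2 background SD. Median spot signals are given in the report as the depth of each array.

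On 5 simulated data sets with the probes' own spread and 200 changed probes each, the fit found 80% of the probes changed by 1.5-fold and 98.4% of those changed by 2-fold in the resistant-against-susceptible comparison of 21843 probes. False calls were 4.79% of all calls. These simulated probes were independent of each other, unlike real ones. The adjustment also sets a looser cutoff on p when more probes are called. The shares found can therefore be too high for the real data, where 18 probes were called.

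The rule for named probes, for arrays without gene names, took the 2 probes with the largest rise and the 2 with the largest fall among those past the threshold. The test, this rule and most alternatives were fixed before the data were examined. Gene lists for defence, terpenoid, phenylpropanoid and cell type genes had also been fixed, but were not run because the files do not pair probes with names. Alternatives changed the background correction, normalization, flags, filter on dim probes, signal summary, dye term, prior variance, array weights, image set block, threshold, starting values and arrays used. The test over all probes, its alternatives, the fit to the scanner values of the authors' positions only and the day of quantification as a block were added after the data were seen. The image set was read from the file headers and treated as a batch. Figures were drawn with matplotlib 3.10.9.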

Results

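Transcript levels were measured in the bark of 40 untreated mature interior spruce trees, hybrids of white spruce (Picea glauca) and Engelmann spruce (Picea engelmannii). By the labels, 20 of the trees were resistant and 20 susceptible to the white pine weevil, an insect whose larvae feed under the bark of spruce and pine shoots. The tissue came from 1 lateral shoot of each tree. Each of 20 two-colour spotted arrays carried RNA of 1 resistant and 1 susceptible tree, with the resistant tree in Cy5 on 10 arrays and in Cy3 on the other 10. No tree was named on more than 1 array, so a replicate was a pair of trees. The resistant trees grew at 1 research station except 1 tree from Barnes Creek, in replicate 2 of the arrays with resistant RNA in Cy5. The array held 21843 spruce cDNA probes of 1 spot each. The median signal of these probes over local background ranged over the arrays from 875 to 2541 intensity units in Cy5 and from 820 to 2881 in Cy3. Spots of bare glass had a median of 82.7 units in Cy5 and 86.3 in Cy3. Between 46.8% and 73.3% of the probes on an array were above their background in both channels. The number of arrays limits the precision of the values below.

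The direct comparison of resistant with susceptible trees asked which bark transcripts differ between untreated trees of the 2 kinds. Among the probes past the threshold, the largest fall was at probe WS02611_L17, whose normalised log2 intensity was 10.16 ± 0.96 (SD, n = 20) in resistant and 11.93 ± 1.64 (SD, n = 20) in susceptible trees. It was lower in the resistant tree in 17 of 20 pairs, and the susceptible level was 3.39-fold the resistant one. Probe WS01020_O08 had 11.49 ± 0.69 in resistant and 12.70 ± 0.99 in susceptible trees (SD, n = 20 each), a susceptible level 2.32-fold the resistant one, and was also lower in the resistant tree in 17 of 20 pairs. The largest rises among the probes past the threshold were smaller. Probe WS00925_G18 was 1.55-fold higher in resistant trees, at 10.42 ± 0.71 against 9.78 ± 0.56 (SD, n = 20 each), and higher in 16 of 20 pairs. Probe IS0012_M22 was 1.51-fold higher, at 10.94 ± 0.71 against 10.35 ± 0.81 (SD, n = 20 each), and higher in 18 of 20 pairs. The files do not pair the probes with gene names, and no genome was used here, so the probes are given by their clone identifiers without a gene or a position.

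These 4 probes passed limma's moderated test with a dye effect per probe and Benjamini-Hochberg adjustment over 21843 probes. Signed values below are log2(resistant / susceptible), the reverse of the authors' value table, which gives susceptible over resistant. The difference at WS02611_L17 was -1.76 (SE 0.334, adjusted p = 0.042), and that at WS01020_O08 was -1.22 (SE 0.228, adjusted p = 0.042). At WS00925_G18 it was 0.63 (SE 0.117, adjusted p = 0.042) and at IS0012_M22 0.59 (SE 0.0928, adjusted p = 0.025). WS02611_L17 was above background in 16 of 20 resistant and 19 of 20 susceptible trees, and WS01020_O08 in 19 and 20. WS00925_G18 was above background in 16 resistant and 11 susceptible trees, and IS0012_M22 in 18 and 13. None of the 4 was saturated on any array. Leaving out 1 array at a time, the call was kept in 7 of 20 cases at WS02611_L17, 7 at WS01020_O08, 8 at WS00925_G18 and 16 at IS0012_M22. Without the pair with the Barnes Creek tree, limma kept IS0012_M22 (adjusted p = 0.0455) but none of the others (adjusted p from 0.0619 to 0.0829).

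**Figure D1:**
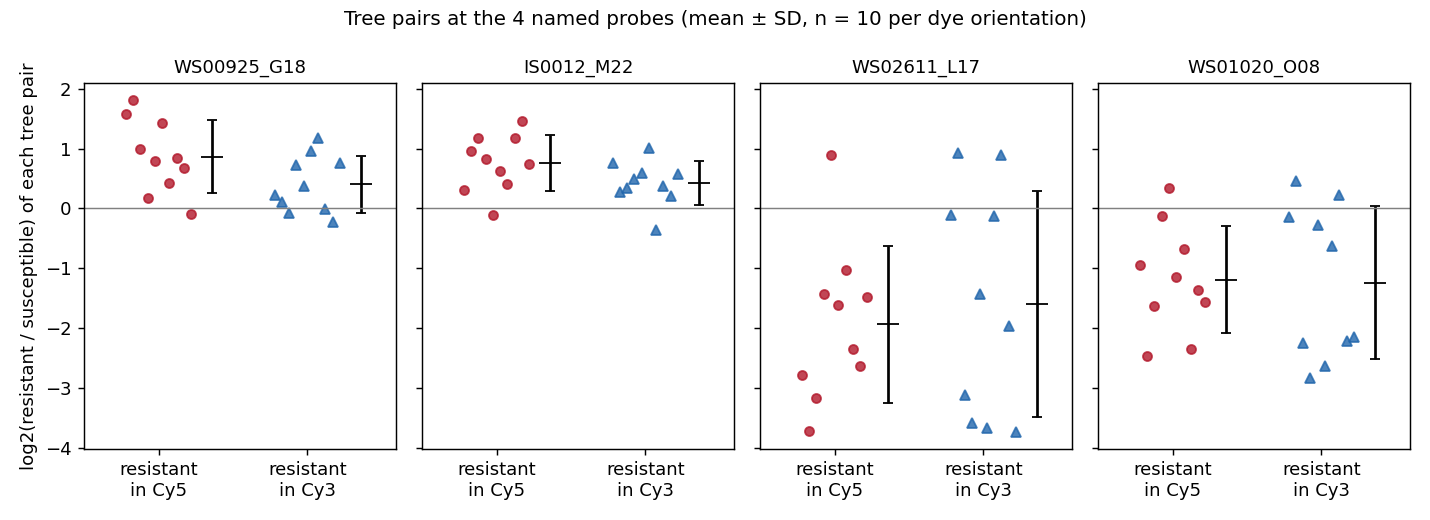
Each point is the normalised log2(resistant / susceptible) of 1 tree pair at 1 of the 4 named probes, with red circles for the 10 arrays with the resistant tree in Cy5 and blue triangles for the 10 with it in Cy3. Black marks give the mean and SD of each set of 10. The pairs at WS02611_L17 range from -3.73 to 0.92, and those at IS0012_M22 from -0.36 to 1.46.

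The arrays fell into 5 image sets by the file headers, of 1, 4, 6, 3 and 6 arrays, and each set of more than 1 array held both dye orientations. With a dye effect for each set, the difference was -1.67 (SE 0.324, adjusted p = 0.108) at WS02611_L17 and -1.15 (SE 0.205, adjusted p = 0.0859) at WS01020_O08. It was 0.63 (SE 0.116, adjusted p = 0.0872) at WS00925_G18 and 0.62 (SE 0.0947, adjusted p = 0.0666) at IS0012_M22, so the sizes moved by less than 1 SE while no call passed the threshold. Within the sets of 4, 6, 3 and 6 arrays, the fitted difference at WS02611_L17 was -0.32, -2.61, -3.43 and -0.62. At WS01020_O08 the values in the same order were -0.14, -1.58, -2.01 and -0.83. Within those sets WS00925_G18 differed by 0.34, 0.69, 0.92 and 0.58, and IS0012_M22 by 0.57, 0.64, 0.99 and 0.47. The set of 1 array allows no fit, and its log ratios were -3.59 at WS02611_L17, -2.82 at WS01020_O08, 0.72 at WS00925_G18 and 0.49 at IS0012_M22. A permutation test of the 19 arrays in the 4 larger sets found that the log ratio at WS02611_L17 differed between sets (p = 0.0016, adjusted p = 0.0064 over the 4 probes). At WS01020_O08 the same permutation test gave p = 0.028 (adjusted p = 0.056). It gave p = 0.76 at WS00925_G18 (adjusted p = 0.76) and p = 0.54 at IS0012_M22 (adjusted p = 0.72).

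In all, 18 of 21843 probes passed the threshold of adjusted p under 0.05, 10 of them higher and 8 lower in resistant trees. The 10 that rose differed by 0.43 to 0.63 on the log2 scale, and the 8 that fell by -0.42 to -1.76. Of the 18, 17 had the same sign in at least 15 of 20 pairs, and 6 were at least 1.5-fold apart, 2 higher and 4 lower in resistant trees. The 18 were picked by a test on these same pairs, so their shared sign is not separate support for the calls. Over all probes the size of the fitted difference had a median of 0.08 and a 95th percentile of 0.34, against a median SD between pairs of 0.43. At unadjusted p under 0.05 there were 2846 probes, 1433 higher and 1413 lower in resistant trees, where independent probes give 1092 by chance. In 99 other splits of the 20 arrays the median was 1025 probes and the highest 2687. With median centring in place of loess the split of the calls was 12 higher and 4 lower, and with a dye effect per image set limma called 0 probes, with 2588 at unadjusted p under 0.05. Leaving out 1 pair at a time moved the count from 0 to 141, as the plot by left-out pair shows. It was 23 without replicate 1 and 12 without replicate 7 of the arrays with the resistant tree in Cy3, and 17 without replicate 4 and 19 without replicate 7 of those with it in Cy5. The other 16 counts, further from 18, are given with the processing alternatives.

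**Figure D2:**
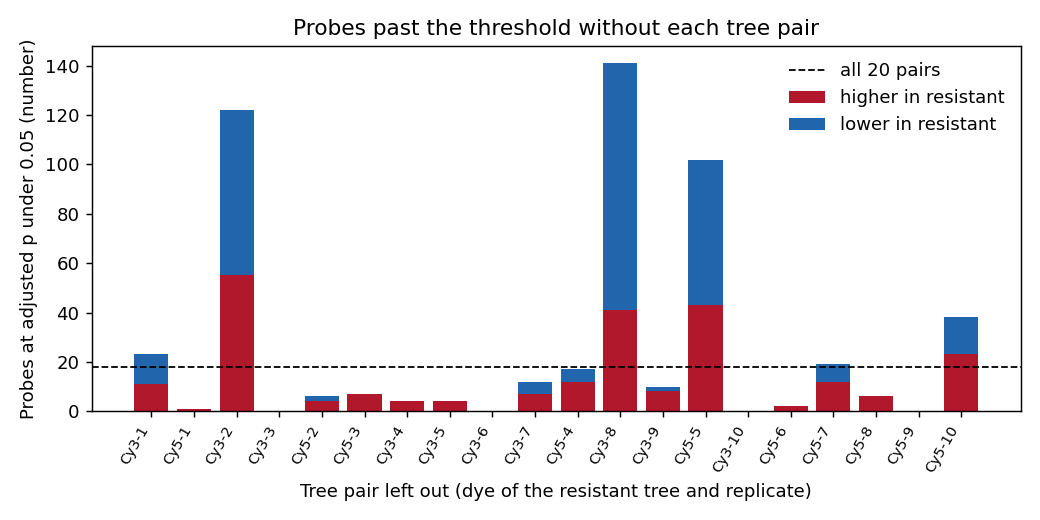
Bars give the number of probes at adjusted p under 0.05 when 1 tree pair is left out, red for probes higher and blue for probes lower in resistant trees. The pair is named by the dye of its resistant tree and its replicate number. The dashed line marks the 18 probes with all 20 pairs. The count is 0 without 4 of the pairs and reaches 141 without replicate 8 of the arrays with the resistant tree in Cy3.

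A test of all probes together, chosen after the counts were seen, asked whether the 2 kinds of tree differ as a whole. The contrast of resistant with susceptible trees held 9.81% of the variation of all log ratios around each probe's mean. All 184756 ways to place the resistant tree in Cy5 on 10 of the 20 arrays gave a median of 5.05%, and 188 of them gave as large a share, an exact permutation p of 0.00102. With the placements exchanged only within image sets, the share was 11.5% against a median of 6.45%, and the exact permutation p was 0.00583 over 4800 placements. Turned to resistant over susceptible, the log ratios of 2 arrays of the same orientation correlated across probes with a median r of 0.0853 over 90 pairs of arrays. The median r was -0.0231 over the 100 pairs of arrays of opposite orientation. These correlations are across probes, which are not independent replicates. The dye effect of each probe was not removed from them, and it raises r within an orientation and lowers it between orientations. The 2 medians therefore do not measure how far tree pairs share a difference.

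**Figure D3:**
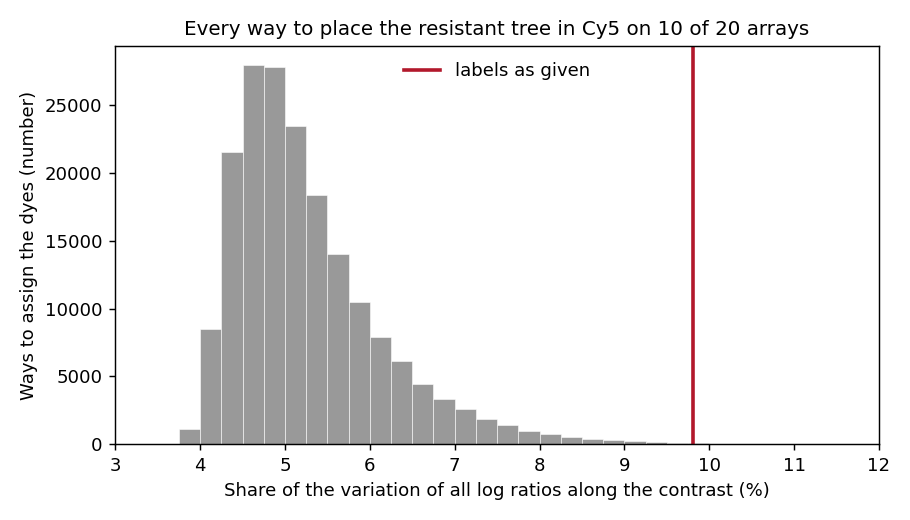
Grey bars count the ways to place the resistant tree in Cy5 on 10 of 20 arrays by the share of the variation of all log ratios, in percent, that lies along the resulting contrast. The red line marks the labels as given, at 9.81%, where the median of all placements is 5.05%.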

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

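The tests of the control spots were chosen after the values were seen. In 22 checks of the 10 arrays of each orientation for a single array far from the rest, 1 array stood out, where chance gives about 1 in 20. Replicate 5 of the arrays with the resistant tree in Cy5 had 411 spruce spots marked as bad by the image software, and the next highest array of that orientation had 233.

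Control spots that the comparison does not use were bright in 1 dye. The GFP spots had a median of 1799 units in Cy5 and 111 in Cy3, and the plasmid vector spots (Bluescript) 5177 in Cy5 and 124 in Cy3. The MGC15287 spots had 8656 in Cy5 and 153 in Cy3. Another 2 controls were bright in Cy3, with 33026 units at MGC1001 and 23683 at MGC1199, against 1018 and 1070 in Cy5. Spots of bare glass had medians of 82.7 in Cy5 and 86.3 in Cy3. Each of these 5 controls was brighter in its own dye on 20 of 20 arrays, on 10 of which that dye carried the resistant tree. The signal thus followed the dye and not the kind of tree. RNA added with each dye, and not from the trees, would give this, but other sources tied to a dye were not tested. Files of the 2 dyes swapped on some arrays are argued against, since 0 arrays had a control brighter in the other dye. What, if anything, was added to the samples is not given in the sources used here.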

How the results depend on the processing

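The test over all probes, its alternatives, the fit to the authors' positions and the block by day of quantification were chosen after the data were seen. The share of variation between resistant and susceptible trees kept an exact permutation p under 0.05 in 15 of 15 alternatives (0.000898 to 0.00583) and 20 of 20 leave-outs (0.000585 to 0.00261). The omission of the Barnes Creek pair was counted in both. Against 18 probes, limma called 36 without background correction, 5 with plain subtraction, 10 with an offset of 10, 45 without every marked spot and 61 among bright probes only. It called 29 with an intensity trend and a robust prior together, 43 with array weights and 8 in the authors' table, where the fitted differences correlated across probes with r = 0.941. A requirement of 1.5-fold left 6. There were 0 with image set or day as a block (2588 and 2630 at unadjusted p under 0.05) and 0 at adjusted p under 0.01. The filter and the omission of marked spots test fewer probes, 13017 and 16556, and the blocks leave fewer residual degrees of freedom. The scanner values of the authors' 18725 positions alone gave 12. For the others the cause was not tested. Rising and falling calls, 10 and 8, were 12 and 4 with median centring, 5 and 0 with subtraction, 8 and 2 with an offset of 10, 6 and 2 in the authors' table, and 41 and 100 without replicate 8 of the arrays with the resistant tree in Cy3.

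Without 1 array, the count went from 0 to 141. For arrays with the resistant tree in Cy5, it was 1 without replicate 1, 6 without replicate 2 (the Barnes Creek tree), 7 without 3, 102 without 5, 2 without 6, 6 without 8, 0 without 9 and 38 without 10. For arrays with it in Cy3, it was 122 without replicate 2, 0 without 3, 4 without 4, 4 without 5, 0 without 6, 141 without 8, 10 without 9 and 0 without 10. The 4 counts of 0 had 2532 to 2713 probes at unadjusted p under 0.05. The named probes kept their direction in every alternative run. The alternatives counted next include the omission of the Barnes Creek pair, which is also a leave-out. Of these, IS0012_M22 stayed past the threshold in 16 of 18, WS01020_O08 in 13 of 18 and WS00925_G18 in 10 of 18. WS02611_L17 did so in 10 of 16. Most omissions of 1 array ended the calls of all but IS0012_M22. Gene lists and their alternatives were not run, for want of gene names. The log ratio of each array already pairs its 2 trees, and the replicate numbers pair nothing further. The signal over background limits dim probes, and 13017 of 21843 were above background in both channels on at least 10 arrays.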

Other observations

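Many probes had a wide ratio in single pairs of trees and did not pass the test between the groups. Each tree was measured by 1 spot per probe on 1 array. A wide ratio in 1 pair can therefore come from the spot or array as well as from the trees. Of 19569 probes with a spot above background, 1926 differed at least 4-fold between the trees of 1 pair or more, and 147 at least 16-fold. Of these 147, 98 also differed at least 4-fold the other way in another pair. In the limma fit 0 of the 147 passed the threshold and 27 had an unadjusted p under 0.05, and the median size of their fitted log2 difference was 0.27. Over all 21843 probes 18 passed and 2846 had an unadjusted p under 0.05. With so few calls among all probes, 0 among 147 says little about their relation to the groups. The share of the 147 at unadjusted p under 0.05 was higher than that of all probes. The susceptible tree was the higher one in the extreme pair at 95 of the 147 probes, and the resistant tree at 52.

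Pairs with a larger gap at WS02611_L17 tended to have a larger one at WS01020_O08. Over the 20 pairs, with the dye effect removed, Pearson's r was 0.893 (permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 6e-05 over 6 relations) and Spearman's rho was 0.878 (permutation p = 1e-05, adjusted p = 6e-05). Without the 2 pairs farthest from the median r was 0.853. Of the other 5 relations, IS0012_M22 against WS02611_L17 passed by r (-0.528, permutation p = 0.016, adjusted p = 0.049) but not by rho (-0.496, permutation p = 0.027, adjusted p = 0.081), and r was -0.324 without 2 pairs. The remaining 4 passed by neither. Within the 2 image sets of 6 arrays r was 0.752 (exact permutation p = 0.0972) and 0.981 (exact permutation p = 0.00417). In all, 108 probes of 19975 had an r over 0.8 with WS02611_L17 across pairs. All 108 were lower in resistant trees by the fitted difference, with a median of -0.63, and 1 of them passed the threshold. They were picked by their r with a probe chosen for its fall over the same pairs. Their shared direction is therefore not separate support for a difference between the groups. Among the 999 most variable probes the median number of partners with an r over 0.8 was 2, and 1.80% had as many as 108. Clustering in 1 print block is argued against, since the fullest block held 6 of the 108 probes and the 95th percentile of random draws was 8. Other patterns of location on the slide were not tested. Susceptible trees were more spread at WS02611_L17, with an SD of 1.64 against 0.96 in resistant trees (permutation p = 0.011, adjusted p = 0.044 over 4 probes), but this lay mostly between image sets. In the sets of 4, 6, 3 and 6 arrays the susceptible means were 10.72, 12.82, 13.13 and 10.76. Within these sets the pooled SD was 1.16 in susceptible and 1.02 in resistant trees (permutation p = 0.64, adjusted p = 0.64), a test added after the first. The ratio sizes had a positive correlation with each array's SD of log ratios, not past adjusted p of 0.05, at WS02611_L17 (Pearson's r = 0.437, permutation p = 0.054; Spearman's rho = 0.388, permutation p = 0.091) and WS01020_O08 (r = 0.451, permutation p = 0.046; rho = 0.436, permutation p = 0.055), over 20 arrays. Adjusted over both probes, p was 0.054 for each r and 0.091 for each rho, and without the 2 arrays farthest from the median r was 0.335 and 0.277.

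Tests of the range of the 2 falling probes were chosen after it was seen. Dividing by each array's SD of log ratios lowered the relative spread of the ratio sizes by at most 2.24%. That SD ranged only from 0.489 to 0.690 over the arrays, so dividing by it could remove little. The small fall follows from this narrow range, so the test cannot decide whether compression that scales all ratios of an array alike contributed. Compression of other kinds was not tested. A dye effect of the image set could move the fall only a little, since both sets of 6 arrays held 3 of each orientation. With a dye effect per set at least 94.4% of the fitted difference was left, which this near balance makes likely in any case. The image set itself stays open, because 63.4% of the variation at WS02611_L17 lay between 4 sets and each pair of trees was in 1 set only. Differences among the trees, as the design names them, may account for the same range, and probes that share sequence were not tested for.

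Of the tests of group differences, the comparison of all probes with other placements and the splits within image sets were chosen after the counts were seen. Chance is argued against for the count of 18 in the fit without a block, though 100 splits cannot exclude it. The real split alone gave as many, 1 of 100 free splits (highest other 2) and 1 of 100 splits within image sets (highest other 1). With the image set as a block the real split called 0 probes (highest other 3), so no call was left to test. At unadjusted p under 0.05, 2 of 100 splits within sets, the real one included, gave at least its 2588 probes (highest other 2622). For the share of variation, 94 of 92378 splits gave 9.81% or more, and the highest other gave 11.6%. The image set as the cause is argued against by p = 0.00583 within sets, dim spots by p = 0.00104 on bright probes only, and 1 tree pair by the highest p of the 20 leave-outs, 0.00261. A difference between resistant and susceptible trees spread over many probes may account for this, as a hypothesis found and tested on the same data.

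A dye effect passed the threshold at 923 probes, 457 of them brighter in Cy5, and 1 of the 18 called probes was among them.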
